A study of Drosophila melanogaster with 2 samples.

How the data were processed

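Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole larvae of Drosophila melanogaster at the wandering stage of the third instar, per the labels, with males and females pooled. The animals carried a transgene for Dif fused at its C terminus to GFP, and an antibody against GFP was used for the precipitation. Dif is the Dorsal-related immunity factor, an NF-κB protein that acts downstream of the Toll receptor in the immune response. The labels give 1 group with 2 biological replicates, numbered 3 and 4, and chromatin sheared by sonication, with a size range of 200 to 275 for replicate 3 and of 200 to 300 for replicate 4. No other genotype, treatment or stage is among the samples, so the design implies a description of bound sites and of replicate agreement. The labels name a possible control experiment, and its libraries were not used here.

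The authors deposited peak lists for 2 genome builds, dm6 and dm3. Per the file headers and the deposited listings, 3 relaxed lists per build held 30000 peaks and background regions each, called in replicate 3, in replicate 4 and in both replicates pooled, against a control. A further list per build held the peaks that passed the irreproducible discovery rate (IDR) threshold, a measure of how well replicates rank the same peaks. It held 4175 peaks in dm6 and 4125 in dm3. The aligner, the peak caller and their versions are not given in the sources used here. The signal of each peak is the authors' own value, its scaling is not given in the sources used here, and it was used to rank, describe or filter peaks within one list and to correlate matched peaks of both replicates, by rank and on the log2 scale. The deposited lists also give a −log10 q value per peak, which lay between 3.26 and 3.74 in the dm6 IDR list. In the dm6 relaxed lists, q was at most 0.01 for 27.5% of pooled regions, 33.6% in replicate 3 and 41.7% in replicate 4. Peaks and background regions of these lists are both called relaxed peaks below. The files hold no read counts, so the depth of each library is unknown, and intervals on shares cover counting error only.

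All 4175 dm6 IDR peaks were also peaks of the pooled relaxed list. They were its 4175 strongest peaks by signal, so taking the strongest pooled peaks in their place gave the same set. A peak of the IDR list need therefore not have a summit in the list of each replicate. The dm6 relaxed lists and the IDR list held peaks on arms 2L, 2R, 3L, 3R, 4 and X and 0 peaks on Y.

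Genes, transcription start sites (TSSs) and gene parts came from Ensembl release 115, and sequence from the Release 6 assembly. As a check of the build, 30565 of 30618 annotated start codons (99.8%) read ATG in that sequence. Analyses used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, with 1-based dm6 coordinates. Peaks were placed by their summits. Replicates were compared through the 4175 strongest peaks of each, and a peak counted as shared when a summit of the other replicate lay within 100 bp. Expected overlap came from 1000 circular shifts of the peaks along each arm, one-sided for overlap and two-sided for genomic features. For dm3 the arm lengths were taken from the last peak, as no dm3 sequence was used here. Arms were compared with their share of the total length by exact two-sided binomial tests. A gene was counted as having a peak when an IDR summit lay within 500 bp of any of its TSSs, among 13945 protein-coding genes on the arms. Gene lists were tested with two-sided Fisher's exact tests against all other protein-coding genes, and also set against 10000 random lists matched on the number of TSSs and gene length. Motif matches on either strand within 100 bp of a summit were compared with a flank of the same size 1000 bp away by exact two-sided McNemar tests. Flanks that overlapped another IDR summit window were left out with their peak. Motif presence was related to signal, and signal to TSS position, by two-sided permutation tests with 100000 resamples. Benjamini-Hochberg adjustment was made over the 20 gene lists, the 15 motifs, the feature classes or the arms, with a threshold of 0.05, and intervals are at the 95% level. Peaks and genes are not independent replicates, so these p-values describe these peak lists.

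On simulated data, 60.3% of 4175 peaks were found shared where 60% had been planted. Gene lists of 25 genes planted at an odds ratio of 6 were called in 95.2% of simulations over 13945 genes, and lists with no effect in 1.10%. These lists were drawn at random from all genes. The rates thus do not cover lists of long genes or of genes with many TSSs, or smaller odds ratios. A motif planted in 10% of 2000 windows was recovered as a gain of 9.95%.

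The gene lists, the motifs, the tests of the report and its alternatives were fixed before the data were examined, with 1 alternative added later. Some tests of the closing section were chosen after. For subsets of the IDR list, flanks had first been screened against the subset alone; this was corrected to all IDR summits after its output had been seen, and the earlier form was kept as the added alternative. The genes named are those of the 20 strongest IDR peaks lying within 500 bp of a TSS and within 100 bp of a summit in each replicate's relaxed list. Up to 4 members of each list with the strongest such peak were added, and Dif, dl, Rel, cact, Tl, Drs, Mtk, DptA, PGRP-SA and BomS1 were always named. Other genes are said to have been chosen after their values were seen. A gene that this rule names is not reported here. Of the symbols on the lists, SgsF was not found in the annotation, and Tor was left out because its symbol was ambiguous. Alternatives covered the summit distance, the number of peaks, the build, each replicate alone, the stronger part of the IDR list, the TSS window, the background of genes, and the window and control for motifs.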

Results

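The data are peak lists from anti-GFP ChIP-seq on whole larvae that express GFP-tagged Dif, in 2 biological replicates of 1 group. The dm6 IDR list held 4175 peaks with a median width of 244 bp. Each replicate's relaxed list held 30000 peaks and background regions. Signal ran from 83.9 to 4992 in the IDR list, and the 100 strongest peaks held 13.1% of its summed signal. With no second group, the questions are where tagged Dif was found and how far both replicates gave the same sites.

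The strongest peak at a TSS was upstream of Coq2, an enzyme of coenzyme Q synthesis, on arm 3R at 8316758 to 8317142, with the summit at 8316937 in intergenic sequence 394 bp from the TSS and a signal of 4992. The next lay between CG3253 and CG4049 on 2R at 24114185 to 24114488, with a signal of 4138, and at the 5′ UTR of Mic26-27 and near CG5916 on 3R at 16146479 to 16146918, with a signal of 3587. Peaks at Vha16-5 and CG12299, Smg5, gus, DUBAI and Tmem18, shot, mura and Gnpat followed, with signals from 2780 down to 1564. The remaining genes at the 20 strongest such peaks were CG8617, eIF2Balpha, Vps13B, GstE12, CG8950, Mov10, CG33169, tun, CG31522, Sec15, rtet, sbb, CG8500 and MtnA, a metallothionein. Coq2 and the CG3253 peak ranked 1 and 2 in each replicate. CG33169 ranked 13 in replicate 3 and 125 in replicate 4.

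Of the 4175 strongest peaks of each replicate, 2283 (54.7%, Wilson interval 53.2% to 56.2%) had a summit of the other replicate's strongest peaks within 100 bp. Circular shifts, used as permutations of the peak positions, gave a mean of 0.638% for replicate 3 and 0.632% for replicate 4, with p = 0.001 in both, the smallest p that 1000 shifts can give. The strongest sites were found in both replicates. Of the 100 strongest peaks of replicate 3, 100% had a summit in the full list of replicate 4, against 12.2% of those ranked 20001 to 30000. In the other direction, 98% of the 100 strongest peaks of replicate 4 had one. Across 8708 matched peaks, signal gave a Spearman rho of 0.649 and a Pearson r of 0.721 on the log2 scale. Of the IDR peaks, 98.0% had a summit in the full list of replicate 3, 87.3% in that of replicate 4 and 85.4% in both. Among the 4175 strongest peaks of each, the shares were 85.8% for replicate 3, 64.0% for replicate 4 and 54.4% for both, so the IDR list lies closer to replicate 3. Over all relaxed peaks, 29.0% of those of either replicate were shared.

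**Figure D1:**
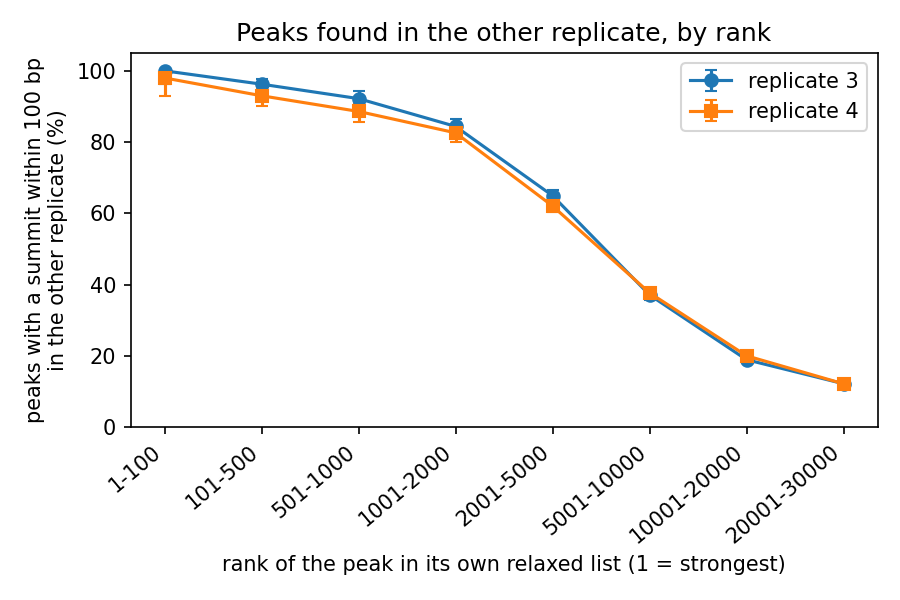
Share of peaks (percent, y axis) with a summit within 100 bp in the other replicate's relaxed list, by rank in their own list (x axis), for replicates 3 and 4, with Wilson intervals as bars. The share falls from 100% and 98% for the 100 strongest peaks to 12.2% in both for ranks 20001 to 30000.

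Most peaks of tagged Dif lay within 500 bp of a TSS, while 46.9% lay within 200 bp. Within 500 bp of an annotated TSS lay 2467 of 4175 summits (59.1%, Wilson interval 57.6% to 60.6%), against 13.6% after circular shifts, a ratio of 4.35. Summits in 5′ UTRs outside that window were 2.47 times as frequent as after shifts, at 1.89%, but with a TSS window of 1000 bp the ratio was 1.20 and did not pass (permutation adjusted p = 0.482). Coding sequence held 28 summits, or 0.671% against 13.7%, and 3′ UTRs held 1.10% against 4.39%. Introns held 27.2% against 39.3% and intergenic sequence 9.03% against 27.4%. These 6 classes had a permutation p = 0.002, the smallest two-sided p that the shifts can give, and an adjusted p of 0.00233. Other exons held 1.01% against 0.810% and did not pass, with a permutation adjusted p of 0.260, but passed with replicate 4 alone (1.22%) and at 200 bp (2.08%). The median distance of a summit to the nearest TSS was 262 bp. The shifts took no account of where reads can be placed in repeated sequence, so the shares after shifts carry this limit.

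IDR peaks were sparse on arms 4 and X. Arm 4 held 12 peaks, or 8.90 per Mb, which was 0.285 times its share by length (exact adjusted p = 5.78e-07, exact binomial test). The relaxed lists include background regions, and there arm 4 was not sparse. It held 394 of the 30000 pooled relaxed peaks (1.31%, exact interval 1.19% to 1.45%), against 1.01% of the length. It also held 384 of those of replicate 3 (1.28%) and 341 of those of replicate 4 (1.14%). Arm X held 629 peaks, or 26.7 per Mb, 0.857 times its share (exact adjusted p = 4.43e-05). It held less still of the relaxed lists, 12.0% of the pooled peaks, 11.9% in replicate 3 and 13.1% in replicate 4, against 15.1% of the IDR list and 17.6% of the length. Arm 2R held 863, or 34.1 per Mb, 1.09 times its share (exact adjusted p = 0.0073). Among the stronger 2087 IDR peaks, 2R no longer passed, with an exact adjusted p of 0.147. Arms 2L, 3L and 3R held 31.9, 31.2 and 32.5 peaks per Mb and did not pass, though 3R passed among the stronger IDR peaks (ratio 1.12, exact adjusted p = 0.00585) and with replicate 4 alone (exact adjusted p = 0.0135). The larvae were of both sexes, so X was present in fewer copies than the autosomes. Whether this accounts for the lower share of peaks on X was not tested, and the peaks were called against a control. The dm3 IDR list held 736, 861, 866, 1024, 13 and 616 peaks on 2L, 2R, 3L, 3R, 4 and X, against 751, 863, 876, 1044, 12 and 629 in dm6. No coordinates were converted between builds.

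Peaks were slightly stronger at promoters. The median signal was 141 in the 2467 peaks within 500 bp of a TSS and 128 in the 1708 other peaks, a ratio of 1.10 (p = 1e-05, the smallest that the permutations can give).

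A peak lay at the TSS of 2127 of 13945 protein-coding genes (15.3%). Genes of the Toll pathway were among them more often than other genes. The antimicrobial peptide genes, several of which this pathway controls, carried 1 peak among 24, against a mean of 0.736 in matched random lists. Toll components and peptide genes were not tested against each other. Of 31 Toll pathway components, 11 had a peak (35.5% against 15.2% of other genes, odds ratio 3.07, interval 1.32 to 6.72, exact adjusted p = 0.0155, Fisher's exact test). The 11 include the tagged gene Dif, where an extra copy may contribute peaks, and its neighbour dl. The list was not tested without them. Dif itself had 2, of which the stronger lay in an intron on 2L at 17428155 to 17428302, 30 bp from a TSS, with a signal of 386. Its neighbour dl, which encodes the NF-κB factor Dorsal, had its stronger peak at 17450320 to 17450563 with a signal of 312, which ranked 1297 in replicate 3 and 72 in replicate 4. The ligand spz, the receptor Tl (3R, 26798938 to 26799181, 5′ UTR, signal 202) and the inhibitor cact (2L, 16325851 to 16326094, intron, signal 185) also had peaks, and PGRP-SA had none. Of 27 components of the Imd pathway, the other NF-κB route of fly immunity, 10 had a peak (odds ratio 3.28, interval 1.34 to 7.59, exact adjusted p = 0.0155). They included imd, with a signal of 419, ben, Tak1 and Rel, which encodes the NF-κB factor Relish and had a signal of 204 in its 5′ UTR on 3R at 9047699 to 9047942. Random lists matched on TSS number and length held a mean of 5.21 genes with a peak for the Toll list and 5.90 for the Imd list. Of these random lists, 99.5% held fewer than the 11 Toll genes and 95.96% fewer than the 10 Imd genes. With a TSS window of 200 bp the Imd list no longer passed (odds ratio 1.58, exact adjusted p = 0.432), and at 5000 bp the Toll list did not (1.26, exact adjusted p = 0.669).

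Among effector genes, Drsl6, named after its value was seen, was the antimicrobial peptide gene with a peak, and Drs, Mtk and DptA had none in the IDR list. The summit lay 485 bp from the Drsl6 TSS and nearer to that of another gene, and with replicate 4 alone no gene of this list had a peak. None of the 15 Bomanin and Daisho genes, among them BomS1, had one. Neither list passed the test against other genes (exact adjusted p = 0.202 and 0.199), though the Bomanin list passed as lower at 5000 bp (exact adjusted p = 0.0136), and random lists of genes matched on TSS number and length held a mean of 0.736 and 0.709 genes with a peak. In the pooled relaxed list, 9 of the 24 and 4 of the 15 had a summit within 500 bp of a TSS, against 50.5% of all protein-coding genes.

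Ecdysone response genes carried peaks most often of the 20 lists. Of 25 ecdysone response genes, which act in the steroid-driven onset of metamorphosis, 20 had a peak (80%, odds ratio 22.4, interval 8.15 to 76.5, exact adjusted p = 2.1e-11). Matched random lists held a mean of 10.5, and 0% of them held more. The odds ratio was 11.9 among the stronger IDR peaks, 12.5 at 200 bp and 14.9 with replicate 4 alone, each past the threshold. E23 (signal 677), tai (523), EcR (487), the ecdysone receptor, and Eip74EF (478) had the strongest. Of 20 insulin and nutrient signalling genes, 9 had a peak (odds ratio 4.56, exact adjusted p = 0.00744), including sima (562), Thor (347) and REPTOR (324), but at 5000 bp the list no longer passed (exact adjusted p = 0.158). Matched random lists for the insulin genes held a mean of 5.19, and 96.25% of them held fewer than 9. Of 85 cytosolic ribosomal protein genes, 29 had a peak (odds ratio 2.90, exact adjusted p = 8.62e-05), among them RpS28a, RpL7, RpL3 and RpL23A. The RpS28a summit lay 485 bp from its TSS, past the 3′ end of the gene. When only the gene with the nearest TSS counted, the ribosomal list still passed, with 25 of 85 (odds ratio 2.62, exact adjusted p = 0.00122). Among the stronger IDR peaks this was lost, with an odds ratio of 0.976 (exact adjusted p = 1).

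Of 13 melanization and clotting genes, 6 had a peak (odds ratio 4.77, exact adjusted p = 0.0229), among them MP1, Hayan, Spn77Ba and Sp7, but at 5000 bp the list no longer passed (exact adjusted p = 0.506). Of 21 JAK-STAT and stress peptide genes, 8 had one (odds ratio 3.43, exact adjusted p = 0.0229), among them dome, Tep2, upd3 and Ptp61F. Of 23 fat body genes, 8 had one (odds ratio 2.97, exact adjusted p = 0.0303), among them GstD1, FASN1, Sesn and Lsd-2. Of 26 embryonic targets of Dorsal, 9 had one (odds ratio 2.95, exact adjusted p = 0.0234), among them brk, sog, dpp and cact, but 13.4% of matched random lists held more. With replicate 4 alone, the JAK-STAT, fat body and Dorsal target lists no longer passed (exact adjusted p = 0.282, 0.213 and 0.0757). Nor did they at 200 bp (exact adjusted p = 0.0804, 0.0557 and 0.0804), 1000 bp (0.0668, 0.0821 and 0.0668) or 5000 bp (0.226, 0.727 and 0.506), and JAK-STAT and fat body genes also lost their calls among the stronger IDR peaks (0.172 and 0.0787).

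Chemoreceptor, digestive enzyme and cuticle genes had no IDR peaks within 500 bp of a TSS. None of 119 olfactory and gustatory receptor genes (exact adjusted p = 3.94e-08), 32 midgut digestive enzymes (exact adjusted p = 0.0234) and 26 larval cuticle protein genes (exact adjusted p = 0.042) had one. Matched random lists held means of 8.88, 1.46 and 1.00, and 77.3% and 64.4% of the random lists for the enzymes and cuticle genes held more than 0. The cuticle call was lost with replicate 4 alone (exact adjusted p = 0.219), when only the gene with the nearest TSS counted (0.0634) and at 5000 bp (0.435). Among the stronger IDR peaks and at 200 bp, those of the cuticle genes (exact adjusted p = 0.252 and 0.113) and the enzymes (0.180 and 0.0700) were both lost. The lists that did not pass were JNK and cell death (6 of 20, kay, hid, Diap1 and egr, exact adjusted p = 0.155), heat shock (7 of 23, stv, Hsp22, Hsc70-3 and Hsc70-4, exact adjusted p = 0.111), and blood cell markers (4 of 22, ush, lz, gcm2 and kn, exact adjusted p = 0.805). Muscle genes (4 of 28, Zasp52, Msp300, Tm1 and Mef2, exact adjusted p = 1), neuronal genes (5 of 28, wit, Fas2, dlg1 and elav among them, exact adjusted p = 0.712) and glue genes (1 of 14, fkh, exact adjusted p = 0.788) did not pass either. Of the lists matched on TSS number and length to the muscle genes, 99.7% held more than their 4, with a mean of 10.4, and for the neuronal genes 97.3% held more than their 5, with a mean of 9.78. The elav peak ranked 625 in replicate 3 and 28646 in replicate 4. With each replicate alone, JNK and cell death genes passed, with 8 of 20 in replicate 3 and 10 in replicate 4, as they did among the stronger IDR peaks (exact adjusted p = 0.0194). Heat shock genes passed with replicate 4 alone, among the stronger IDR peaks and at 1000 bp (exact adjusted p = 0.00972, 0.0339 and 0.0497).

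When the background was limited to the 7043 genes with a pooled relaxed peak at a TSS, the ecdysone list was the single list of the 20 that still passed, with 20 of 24 genes and an odds ratio of 11.7. The odds ratio of the Toll components was then 1.70 (exact adjusted p = 0.363) and that of the Imd components 1.93 (exact adjusted p = 0.363). That of the JAK-STAT list did not fall, at 3.71 with 8 of 13 genes (exact adjusted p = 0.188), against 3.43 among all genes.

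**Figure D2:**
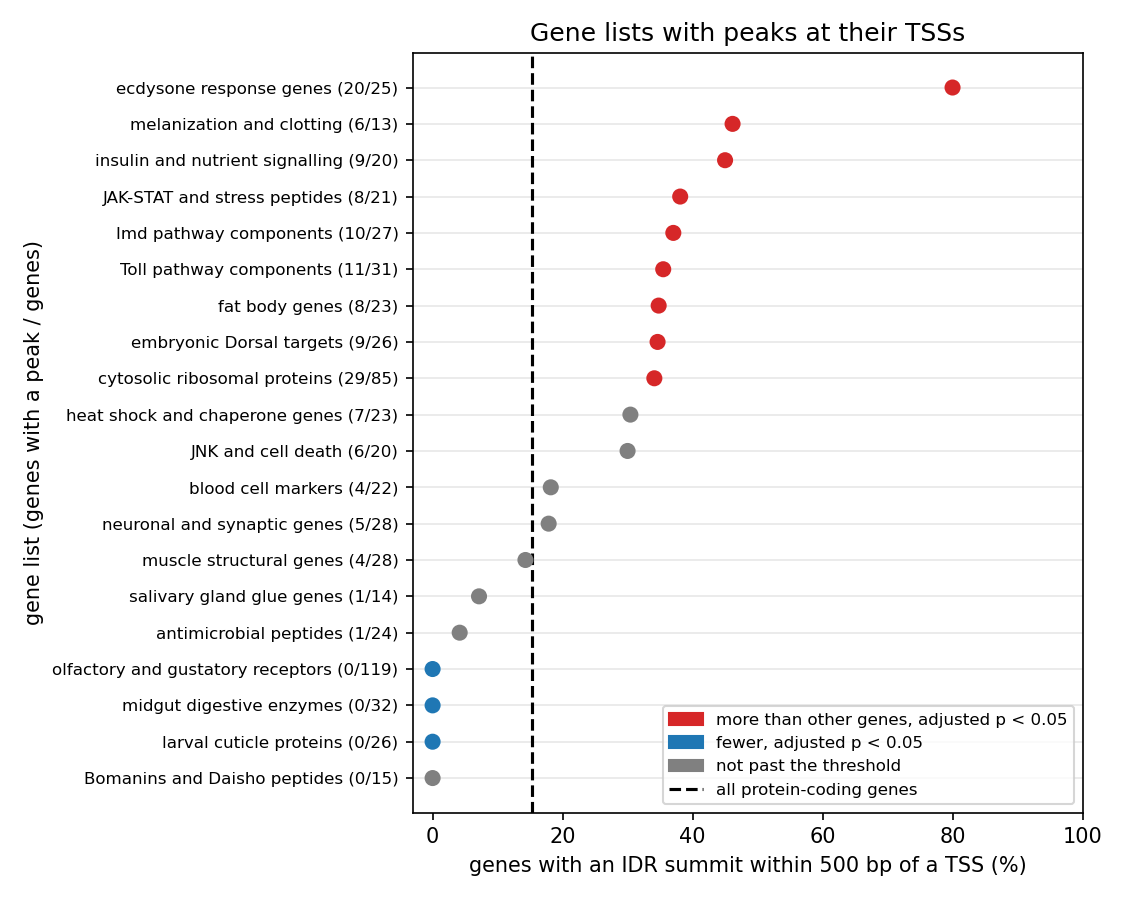
Share of genes in each of the 20 lists with an IDR summit within 500 bp of a TSS (percent, x axis), with the number of genes in brackets; red points are lists with more peaks than other genes past the threshold, blue points lists with fewer, and grey points the rest. The dashed line marks all protein-coding genes, at 15.3%, and ecdysone response genes lie highest, at 80%.

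Summits held GAGA sites far more often than their flanks, and κB sites, the sequences NF-κB factors recognise, less often. The GAGA motif (GAGAGAG, bound by GAGA factor) was present at 34.0% of 3853 summits and 3.30% of flanks, a ratio of 10.3 (exact adjusted p = 9.26e-279, exact McNemar test). The ratio was 16.9 within 50 bp, 6.06 within 250 bp and 5.11 against dinucleotide-shuffled windows (34.6% against 6.78%). The broad κB motif was present at 47 summits (1.22%) against 2.26% of flanks, a ratio of 0.54 (exact adjusted p = 0.00105). The Dif-type motif was present at 5 summits, a ratio of 0.278 (exact adjusted p = 0.0145), the Relish-type at 3, a ratio of 0.25 (exact adjusted p = 0.0439), and the Dorsal-type at 21, a ratio of 0.724 (exact adjusted p = 0.345). Against the shuffled windows, the broad κB ratio was 0.945 (exact adjusted p = 0.903). The Dif-type call was lost under every alternative, and the Relish-type call under all those fixed beforehand but the weakest pooled peaks as control (ratio 0.158). The broad κB call was also lost with replicate 3 alone (ratio 0.688, exact adjusted p = 0.0601) and beyond 500 bp from a TSS (0.536, exact adjusted p = 0.124), and the Dorsal-type motif passed within 50 bp (0.316, exact adjusted p = 0.0244).

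Other motifs differed too. Motif 1, a core promoter element, had a ratio of 5.67 (exact adjusted p = 4.51e-10), DRE 2.27 (exact adjusted p = 0.000293), the E-boxes CACGTG and CAGCTG 1.49 each (exact adjusted p = 0.0056 and 8.8e-10). GATA (0.696), Stat92E (0.552), EcR sites (RAGGTCA, 0.50) and TATA (0.50) were less frequent at summits, each past the threshold. Zelda and AP-1 sites did not pass (exact adjusted p = 0.132 and 0.568). Zelda did pass against shuffled windows (ratio 1.69), against the weakest pooled peaks (1.58) and beyond 500 bp from a TSS (2.13, exact adjusted p = 0.0466). In the latter peaks, with flanks screened within them alone, Zelda did not pass (1.88, exact adjusted p = 0.0817). Against shuffled windows, TATA turned to 2.15 and CACGTG to 0.736, both past the threshold in this opposite direction (exact adjusted p = 3.93e-10 and 0.00874). GATA turned to 1.03 there and did not pass (exact adjusted p = 0.601). Beyond 500 bp from a TSS, Motif 1 and DRE had ratios of 0.50 each and no longer passed, nor did CACGTG (1.33, exact adjusted p = 0.297) and EcR sites (0.675, exact adjusted p = 0.217). CACGTG was also lost within 50 bp (1.17, exact adjusted p = 0.456) and 250 bp (1.13, exact adjusted p = 0.238), TATA within 250 bp (0.905, exact adjusted p = 0.0596) and DRE among the stronger IDR peaks (1.69, exact adjusted p = 0.172). The ratios of Motif 1 and DRE were 14.2 and 11.3 against shuffled windows, and that of Motif 1 was 2.84 against the weakest pooled peaks.

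GAGA sites went with peak strength. They were present in 53.8% of the strongest of 5 equal bins of the IDR list, 44.2%, 31.5% and 25.5% of the next bins and 18.1% of the weakest, with a Spearman rho of 0.272 across peaks (p = 1e-05, the smallest that the permutations can give, adjusted p = 0.00015). Motif 1 went the other way, from 1.20% to 2.99% (rho −0.0577, permutation adjusted p = 0.000825), but not beyond 500 bp from a TSS (rho 0.00732, permutation adjusted p = 0.899). For the other 13 motifs no relation passed, and the broad κB motif had a rho of 0.00634 (permutation adjusted p = 0.853).

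**Figure D3:**
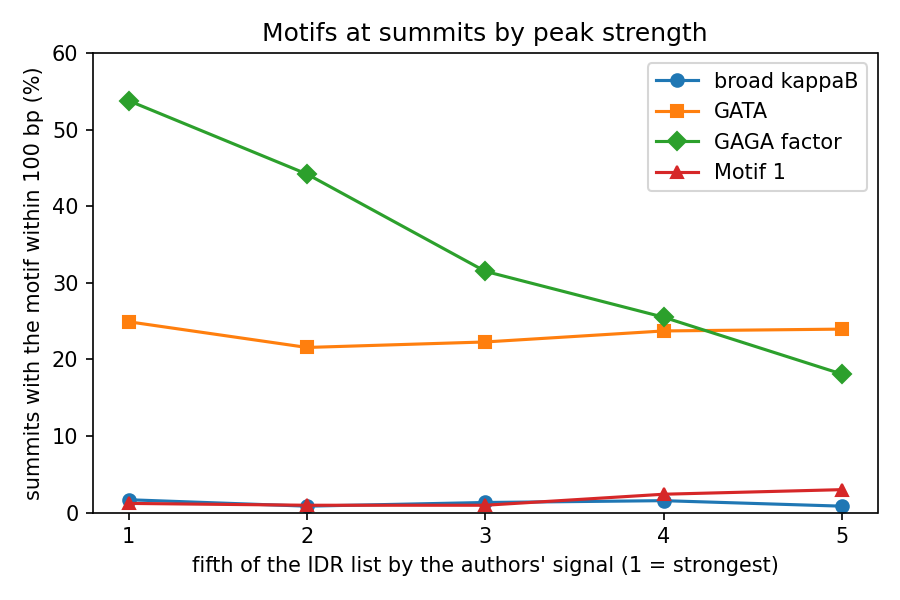
Share of IDR summits with a motif within 100 bp (percent, y axis) in 5 equal bins by the authors' signal (x axis, 1 is strongest), for 4 of the 15 motifs. GAGA sites fall from 53.8% to 18.1%, and the broad κB motif stays between 0.838% and 1.68%.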

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

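Peaks outside the 6 arms appear in the dm3 lists. They enter no comparison by arm, and are counted in the dm3 total of 4125 and in the dm3 overlap of replicates. There were 9 in the IDR list, 66 in the pooled list, 63 in that of replicate 3 and 63 in that of replicate 4, each above the 3 counts that a count of 0 allows. They were flagged because they lie on dm3 sequences outside the arms compared. No coordinates were converted, so whether dm6 places these sequences on its arms was not examined. In the dm3 IDR list 7 of the 9 lay on Uextra, 1 on 2RHet and 1 on 3LHet. The dm6 lists hold 0 peaks outside the arms.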

How the results depend on the processing

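Of 455 alternative values, 328 kept their direction and side of the threshold, 66 lost their call, 15 gained one, 14 moved and 32 reversed, of which 23 passed in neither form. The cause was not tested unless stated. Below, ratios and shares lost their call unless marked as reversed, ranges did so with at least 1 replicate, and rank agreement and counts moved. The values for 3R, other exons, JNK, heat shock, Bomanins and Zelda, and for Dorsal-type sites within 50 bp, instead gained a call unless marked as reversed. All alternatives but 1, chosen after seeing the data and given last, were fixed beforehand, and overlap between replicates stayed past its threshold under each one tried for it. Taking the strongest pooled peaks moved nothing, as they are the IDR list, so these values are among the 328 by construction. The 328 also include counts and rank agreement, which have no threshold and were kept when they stayed within a set range. Read depth is unknown, so its effect could not be measured. Each replicate alone gives peaks without the IDR step. Relish-type sites had 0 matches beyond 500 bp from a TSS, so no relation with strength could be computed there. No paired analysis was possible because there is 1 group.

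Rank agreement was 0.692 (Spearman) and 0.748 (Pearson) at 50 bp, 0.591 and 0.695 at 250 bp, and 0.490 and 0.563 in IDR peaks alone, which cover a narrower range. Windows of 5000 bp gave 4660 genes and the stronger IDR peaks, fewer by construction, 1174.

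Over each replicate alone, ranges were 0.814% to 1.22% for other exons, 32.6 to 33.4 per Mb for 3R, 30.8 to 32.1 for 2L and 31.3 to 32.6 for 3L (both reversed), and odds ratios of 1.80 to 3.34 for JAK-STAT, 2.03 to 2.89 for fat body, 3.62 to 5.76 for JNK, 2.37 to 3.70 for heat shock, 2.56 to 3.39 for Dorsal targets, 0 to 0.229 for cuticle and 0.957 to 1.48 for neuronal genes (reversed). Motif ratios were 0.467 to 0.50 for Dif-type, 0.364 to 0.467 for Relish-type and 0.614 to 0.688 for broad κB.

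In the stronger IDR peaks, 2R had 16.6 and 3R 17.4 peaks per Mb, and other exons 0.815% (reversed). Odds ratios were 2.56 for JAK-STAT, 3.03 for fat body, 4.68 for JNK, 3.85 for heat shock, 0 for cuticle and midgut enzymes, and, reversed, 0.976 for ribosomal proteins and 1.82 for muscle, and 1 list was called lower. Motif ratios were 0.375 (Dif-type), 0 (Relish-type) and 1.69 (DRE), and reversed at 1.02 (AP-1).

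With a TSS window of 200 bp, other exons held 2.08%. Odds ratios were 1.58 (Imd), 2.78 (JAK-STAT), 3.05 (fat body), 2.57 (Dorsal targets), 0 (cuticle, midgut) and 0.330 (blood cells, reversed), with 5 lists called higher and 1 lower. At 1000 bp, 5′ UTRs held 0.527% and other exons 0.359% (reversed), and ratios were 2.78 (JAK-STAT), 2.41 (fat body), 2.39 (Dorsal targets) and 2.91 (heat shock). At 5000 bp they were 1.26 (Toll), 1.71 (melanization), 2.19 (JAK-STAT), 1.28 (fat body), 0.597 (cuticle), 1.46 (Dorsal targets), 2.44 (insulin), 0 (Bomanins) and, reversed, 0.930 (blood cells) and 0.797 (neuronal), with 3 lists called higher. The nearest gene alone gave 0 for cuticle and 1.04 for muscle (reversed).

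Among genes with a relaxed peak, odds ratios were 1.70 (Toll), 1.93 (Imd), 3.47 (melanization), 3.71 (JAK-STAT), 1.54 (fat body), 1.40 (ribosomal), 2.08 (Dorsal targets), 2.61 (insulin), 0 (cuticle, midgut, receptors) and, reversed, 0.924 (blood cells), 1.32 (muscle) and 0.963 (neuronal), with 1 list called higher and 0 lower.

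Motif ratios within 50 bp were 0.222 (Dif-type), 0.143 (Relish-type), 0.316 (Dorsal-type) and 1.17 (CACGTG), and within 250 bp 0.553, 0.581, 1.13 (CACGTG), 0.905 (TATA) and 0.975 (Zelda, reversed). Against shuffled windows they were 0.833 (Dif-type), 0.273 (Relish-type), 0.945 (broad κB) and 1.69 (Zelda), and reversed at 1.03 (GATA), 0.736 (CACGTG), 2.15 (TATA) and 1.85 (Dorsal-type). Against the weakest pooled peaks they were 0.417 (Dif-type), 1.58 (Zelda) and 1.18 (AP-1, reversed). Beyond 500 bp from a TSS they were 0.50 (Dif-type), 0 (Relish-type), 0.536 (broad κB), 2.13 (Zelda), 1.33 (CACGTG) and 0.675 (EcR), and reversed at 0.50 (DRE, Motif 1). The rank correlation with strength there reversed at 0.00732 (Motif 1), 0.0122 (GATA) and 0.00550 (CAGCTG); within 500 bp it reversed at 0.0142 (Dorsal-type) and 0.00687 (AP-1). With flanks screened only within the peaks beyond 500 bp, added after seeing the data, motif ratios were 0.40 (Dif-type), 0.533 (broad κB), 1.24 (CACGTG) and 0.638 (EcR), and reversed at 1.11 (Dorsal-type), 0.40 (DRE) and 0.308 (Motif 1).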

Other observations

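The tests on promoters for GAGA sites and on both explanations for the ecdysone genes were chosen after their results had been seen. Counted over whole gene bodies and 500 bp each side, the genes with the most IDR peaks, named after their values were seen, were Eip75B with 22, Tlk with 17, tara with 16, EcR with 15, and mam and ush with 14 each. Eip74EF, Mnt, Mur2B, shn and tai had 13 each, sbb 12 and CHES-1-like 11. The br gene lies inside Mur2B, so peaks there count for both. Transposable elements held 4 of 4175 IDR summits (0.0958%), against 5.84% after circular shifts (permutation p = 0.002, the smallest two-sided p that 1000 shifts can give). The shifts took no account of where reads can be placed in repeated sequence. This difference therefore does not show that tagged Dif avoids these elements.

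The 25 ecdysone response genes held 126 IDR peaks in their gene bodies. Gene length does not account for this, as 95% of 10000 random lists matched on TSS number and length held 18 to 60 and the highest held 100. The sum was also above matched lists limited to genes with a relaxed peak at a TSS. The 24 ecdysone genes with one held all 126 peaks, against 22 to 65 for 95% of those lists and 99 in the highest. For peaks at a TSS, the odds ratio among genes with a relaxed peak there was 11.7 (interval 3.90 to 46.9). Relaxed peaks come from the same libraries, include background regions and lie at a TSS of 50.5% of all protein-coding genes. Promoters that are broadly marked are therefore not excluded as an explanation. No biological explanation was tested, and a role of the hormone pulse in these larvae stays open, as the samples hold 1 stage.

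GAGA sites were 10.3 times as frequent at summits as in flanks, and 5.11 times as frequent as in shuffled windows. Promoter position does not account for this: beyond 500 bp from a TSS the ratio was 11.2 (interval 8.64 to 15.2), or 8.33 with flanks screened within those peaks alone, the form used before a correction made after its output had been seen. Summits without GAGAGAG had a broad κB ratio of 0.515 against flanks (interval 0.333 to 0.763). The upper bound lay below 1, as set in advance, so these summits held no excess of κB sites over flanks. A κB signal hidden in them is not excluded, as shuffled windows were not tried there. Over all summits the broad κB ratio was 0.54 against flanks and 0.945 against shuffled windows. A gathering of simple repeats stays open, as CACACAC had a ratio of 2.74 (interval 2.42 to 3.12), between the bounds set in advance, and CGCGCGC 3.66 (interval 2.63 to 5.33), while ATATATA had 0.389 and AAAAAAA 0.693. Sites that many proteins occupy, or that any GFP precipitation recovers, may give such a pattern, and with no control libraries used here this was not tested; no biological explanation was tested.

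The stronger peak at a Dif TSS is of interest because the line carries a Dif transgene. Dif and 10000 bp each side held 33 pooled relaxed peaks, which include background regions, against a median of 12 in 513 other genes. Those genes were matched on TSS number and length. Dif held more than 95.1% of them, where 95% had been set in advance. The bound was met only narrowly: the share was 94.9% when Dif itself was counted among the matched genes, as it had been before a correction made after that value was seen, and it was 97.5% in replicate 3 (41 peaks) and 94.5% in replicate 4 (30 peaks). An extra copy of the region may thus contribute, and a locus rich in peaks for another reason is not excluded, as the extent of the transgene is not given in the sources used here. The peak is not one of the GAGA-containing class, with 0 matches of GAGAGAG in its window against 34.6% of all IDR windows with one.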
